A study of Caenorhabditis elegans with 2 samples.

How the data were processed

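Chromatin immunoprecipitation followed by sequencing was carried out by the submitters on whole Caenorhabditis elegans young adults, 63 hours old per the labels, that carried an EGFP tag on the protein of the gene Y79H2A.3 and were synchronised by starving hatched larvae. Chromatin was sheared by sonication and precipitated with an antibody against GFP, per the labels. The study has 1 group of 2 biological replicates, numbered 1 and 2 in the labels. There is no second condition, so no comparison between groups was made. No control precipitation or input was analysed here.

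The deposited data used here are 8 peak lists on the ce11 assembly, per the labels. Of these, 4 are thresholded lists and 4 are ranked lists, and each kind covers replicate 1 alone, replicate 2 alone, the pooled reads, and the comparison of the replicates. The thresholded list from the comparison of the replicates is called conservative in its file name and was taken as the main list. The aligner, the peak caller and the control used are not given in the sources used here. Each peak has a deposited score, which rises as the irreproducible discovery rate (IDR) falls, and a deposited signal value, the authors' own peak height, whose scale is not stated. The signal value was used to rank peaks and compare heights within a list, and to relate heights at the same sites between the replicates, without rescaling. The ranked lists also hold a deposited −log10 of the global IDR. Every peak in the thresholded lists had a −log10 global IDR of 2 or more in its ranked list, that is an IDR of 0.01 or less. The ranked list from the comparison of the replicates holds the signal value of each replicate in 2 columns, which do not say which replicate is which. At the tallest conservative peak, the first column equals the value in the list of replicate 1 (161) and the second that in replicate 2 (216). The lists have 120 columns in all, of which 66 were not used. The files give no read counts, so the depth of each library is unknown and no counting error per peak could be given.

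Peak positions were read as deposited and are printed counting from 1. The chromosome lengths of the reference genome held every peak, and gene models came from Ensembl release 115 for the matching WBcel235 assembly, limited to the 6 nuclear chromosomes. A summit was placed in a promoter window when it lay between 1000 bp upstream and 200 bp downstream of any annotated transcript start, noncoding genes included. A gene counted as bound when its window held a summit. Remaining summits were assigned in order to coding exons, UTR or noncoding exons, introns and intergenic sequence.

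Overlap of the replicate lists (at least 1 bp) was set against 1000 random placements of the other list within its chromosomes, one-sided. Annotation shares were set against 1000 random placements of the summits within their chromosomes, two-sided, with Benjamini-Hochberg adjustment over the classes. The smallest p these placements can give is 0.001 one-sided and 0.002 two-sided. Shares of peaks per chromosome were tested with exact binomial tests. Gene lists, 28 in number and fixed before the data were examined, were tested with Fisher's exact test, two-sided, against all other nuclear genes, with Benjamini-Hochberg adjustment over the lists. Each 6-mer, on either strand, was scored as present or absent within 50 bp of each summit and within 50 bp of a point 300 bp to a randomly drawn side, and tested with the exact McNemar test. The 10 with the smallest p among those more frequent at summits on chromosomes I, III and V were then tested on chromosomes II, IV and X, with adjustment over those 10. Peak heights were compared with a permutation test of the difference in medians (100000 resamples). Shares have Wilson 95% intervals, or exact ones for gene lists, and these cover counting error over peaks or genes only. Peaks and genes are not independent replicates, and every p measures these lists, not the spread between animals. A threshold of 0.05 was used.

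The genes named were chosen by a rule fixed before the data were examined. It takes the 25 peaks of highest signal value with the genes in whose windows they lie or else the nearest transcript start, up to 4 bound members of highest signal value per list, Y79H2A.3, and the 5 highest peaks of each replicate list that the other lacks. Peaks of other genes named later were picked after their values were seen, which is said there.

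The tests of promoter share, gene lists, 6-mers, peak height and replicate overlap were tested on simulated data over 20 runs; the chromosome tests and the other annotation classes were not. With peaks placed at random, the promoter test over 46890 genes passed the threshold in 0 runs, the 28 gene lists gave 3 calls in 560 tests, and the 6-mer test on 1021 peaks gave 0 calls. In these runs summits were placed independently, while the real summits are clustered and many lie in windows of several genes. The rate of false gene list calls on such clustered data was not measured. Peaks planted on 20 ribosomal protein genes were called in 20 of 20 runs, with 8 calls of other lists, and a 6-mer planted at 15% of summits was recovered in 20 of 20. With heights unchanged the height test passed in 3 of 20 runs, and with promoter peaks raised 1.5-fold in 20. Of 200 peaks planted in both replicate lists, at least 200 were found shared, against at most 3 without planting. Alternatives covered other lists, each replicate alone, taller peaks, promoter windows, random placements, gene assignment, backgrounds and flanks. Uniqueness of sequence was the percent of 31-mers that occur once in the genome. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.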

Results

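Y79H2A.3 encodes a protein that the reference annotation describes as containing C2H2-type zinc fingers. Its sites were mapped in whole young adults by precipitating the EGFP-tagged protein, in 2 biological replicates. The conservative list held 1021 peaks, the pooled list 934, replicate 1 alone 442 and replicate 2 alone 393. In the conservative list, 976 peaks had a width of 296 bp, and the median signal value was 82.9. Some of its peaks overlap one another, and 960 remained with overlapping peaks counted once. The depth of the libraries is unknown. No control and no other GFP precipitation was analysed here, so sites shared by many GFP precipitations in worms were not set apart, and a bound gene below is a gene with a peak in its window.

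Both precipitations found many of the same sites. Of the 442 peaks of replicate 1, 219 (49.5%) overlapped a peak of replicate 2, and of the 393 peaks of replicate 2, 228 (58.0%) overlapped a peak of replicate 1. Random placements gave a mean of 1.07 and at most 6 shared peaks in the first direction, and 0.985 and at most 7 in the second (permutation p = 0.001 each, the smallest these placements can give). Summits of shared peaks lay a median of 24 bp apart in replicate 1. Shared peaks were taller, with a median signal value of 65.5 against 49.7 for the other peaks of replicate 1, and 71.8 against 55.3 in replicate 2. Of the 223 peaks found only in the list of replicate 1, 210 overlapped some peak of the ranked list of replicate 2, and 169 overlapped a peak of the conservative list. No random placement was made for these counts. That ranked list holds 45724 peaks, and the conservative list draws on replicate 1 as well, so neither count is independent evidence of a shared site.

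Peak heights in the replicates were related at shared sites. Across the 219 overlapping pairs, Pearson's r of the log10 signal values was 0.67 and Spearman's rho was 0.66. These are values across peaks, which are not independent replicates, and no p is given. At the 1021 conservative sites, the 2 replicate columns had r = 0.64 and rho = 0.43, and 98.0% of sites differed by less than 2-fold. These sites were chosen by IDR for likeness between the same replicates, so their closeness in height is partly fixed by the choice. Over all 77086 ranked sites, r was 0.28. The highest peaks of replicate 1 without a partner lay in C44E4.5 on chromosome I (4608268 to 4608353, signal value 111), near hmg-12 on II (11917588 to 11917867, 101.2), near F25B5.5 on III (5943746 to 5944025, 96.3), upstream of F52B11.2 on IV (14083573 to 14083852, 83.3) and near F27B3.6 on III (6575253 to 6575532, 82.0). Those of replicate 2 lay near Y102A11A.11 on X (2057878 to 2058141, 116), in C44E4.5 on I (4608373 to 4608449, 95.1), at ZK484.9 on I (6082708 to 6082971, 93.6), at 4047927 to 4048190 on II (92.7) and near Y41E3.460 on IV (15059215 to 15059478, 87.2). The C44E4.5 peaks of the replicates lie side by side without touching, and both overlap 1 conservative peak (4608268 to 4608390, signal value 214). Its replicate columns hold the same values, 111 and 95.1. Of the peaks named here, all but that near Y41E3.460 overlapped a peak of the conservative list.

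**Figure D1:**
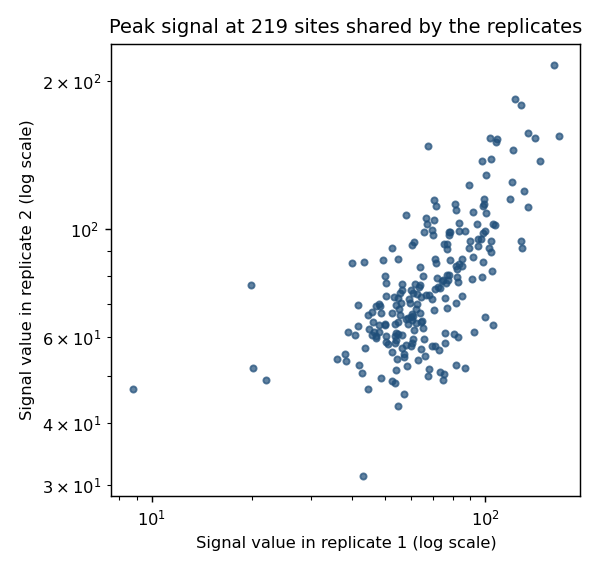
Signal value of each peak in replicate 1 (horizontal, log scale) against the overlapping peak in replicate 2 (vertical, log scale); each point is 1 of 219 shared sites. Taller peaks in replicate 1 tend to be taller in replicate 2 (r = 0.67).

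The tallest peak (chromosome III, 3867484 to 3867662, signal value 378, with 161 and 216 in the replicate columns) lay 287 bp upstream of rpl-3, a gene for a protein of the large ribosomal subunit. The next lay 56 bp upstream of tasp-1 on III (334), which shares its upstream region with K01G5.10. Of the 25 tallest peaks, 19 were in a promoter window and 15 in that of a protein-coding gene. Signal values in this set ran from 209 to 378.

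Among these 25, the mog-4 upstream region on II (298) belongs to a helicase gene of germline sex determination. The peak 3 bp from the start of gpi-1 on I (259), the glucose-6-phosphate isomerase gene, and that upstream of rpa-2 on I (257), a replication protein A gene, were next among coding promoters. The shared upstream region of F44E5.4 and F44E5.5 on II (249) serves a pair of Hsp70 genes. Others lay upstream of rpl-15 and K11H12.8 on IV (247), pgl-3 on V (245), a P granule gene, mtcu-2 on II (245), eel-1 on IV (244), a ubiquitin ligase gene, rpi-2 on IV (231), kin-35 on I (228) and K12H4.5 on III (214), and just inside maph-1.3 on III (240.2). The lea-1 peak on V (233) lay upstream of a transcript start inside that gene. The snoRNA gene ZK994.7 on V had a peak of 233, and the noncoding RNA gene C46C2.12 on IV a peak of 288. At IV 15896006 and IV 16458434, peaks lay among piRNA genes, among them 21ur-963 (297) and 21ur-9399 (227). The 6 without a promoter window were nearest to Y105E8B.9 on I (302), fbxa-190 on X (290), tos-1 on V (253 and 209), zip-11 on IV (214) and C44E4.5 on I (214). In 10 of the 25, fewer than 50% of 31-mers occur once in the genome, against 85 of all 1021 peaks.

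Peaks lay at promoters. A summit in a promoter window was found for 649 of 1021 peaks (63.6%, Wilson 95% interval 60.6 to 66.5), against a mean of 37.9% and at most 42.3% in random placements (permutation p = 0.002, adjusted p = 0.0025, two-sided). UTR or noncoding exons held 10.2% of summits against 3.68% at random, coding exons 6.27% against 17.5% and introns 5.78% against 25.5% (each permutation p = 0.002, adjusted p = 0.0025). The intergenic share of 14.2% against 15.4% did not pass the test (permutation p = 0.318, adjusted p = 0.318). The classes exclude each other, so an excess in promoters lowers the share left for the others. Shares among the summits outside promoters alone were not tested. Many of the annotated starts belong to noncoding genes, and 478 peaks lay in the window of a protein-coding gene. In all, 1032 of 46890 nuclear genes (2.20%) were bound, 575 of them protein-coding. Of the 649 promoter peaks, 291 lay in the windows of several genes, so gene lists share peaks and are not separate sets of sites. Shared peaks include those of hsp-110 with rpn-3, pos-1 with vha-18 and srz-97 with clec-57. Among others, picked after their values were seen, are eif-2Bgamma with the small nuclear RNA gene sup-39, where the summit lies 866 bp upstream of the first and 44 bp past the start of the second, lin-54 with rpl-12, and alg-5 with his-67.

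Relative to the nearest protein-coding transcript start, 377 summits (36.9%) lay within 1000 bp upstream, against 18.6% of random sites, and their median distance was 243 bp. The bin of 250 bp just upstream of the start held 19% of summits against 5.95% of random sites.

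**Figure D2:**
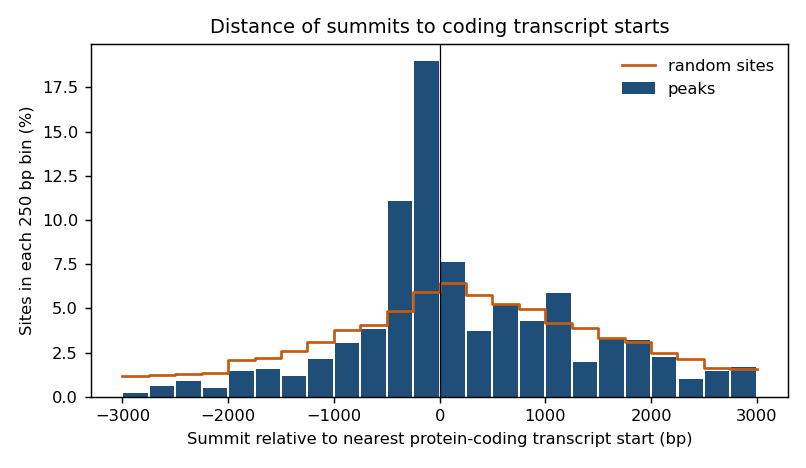
Position of summits relative to the nearest protein-coding transcript start (horizontal, bp, negative is upstream) and percent of sites per 250 bp bin (vertical); bars are the 1021 peaks, the line is random sites on the same chromosomes. The 250 bp just upstream of the start hold 19% of peaks and 5.95% of random sites.

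Genes for small structural RNAs were bound far more often than other genes. Of 612 tRNA genes, 94 were bound (15.4%, exact 95% interval 12.6 to 18.5) against 2.03% of other genes (odds ratio 8.77, Fisher's exact p = 2.91e-50, adjusted p = 8.14e-49). Of 346 small nucleolar RNA genes, which guide RNA modification, 66 were bound (19.1%, odds ratio 11.1, adjusted p = 2.07e-40 by Fisher's exact test). Of 129 small nuclear RNA genes, 19 were bound (14.7%, odds ratio 7.80, adjusted p = 5.07e-10, Fisher's exact test), and of 30 spliced leader RNA genes, which supply the leader for trans-splicing, 6 were bound (20%, odds ratio 11.2, adjusted p = 0.000132). The last 2 lists overlap, since spliced leader genes are annotated as small nuclear RNA genes. Of the 79 peaks in tRNA windows, 75 had a summit within 100 bp of the tRNA gene, and of 68 in small nucleolar RNA windows, 56. Peaks also in the window of a protein-coding gene were 17 of the 79 and 27 of the 68. For small nuclear RNA genes they were 10 of 17, and that list was not tested without such peaks. In single replicates the odds ratio of tRNA genes was 4.80 (27 bound, replicate 1) and 4.67 (23 bound, replicate 2), and both passed. Spliced leader genes did not pass with peaks assigned to the nearest start (Fisher's exact adjusted p = 0.0543).

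The tallest tRNA peaks lay at WBGene00023221 on V (233, a summit 899 bp upstream), WBGene00006314 on III (149), WBGene00014275 on X (145) and WBGene00014333 on X (126), genes without symbols in the annotation. Those of small nucleolar RNAs were at K11H12.12 and K11H12.13 on IV (247), which share the rpl-15 peak, ZK994.7 on V, which shares the WBGene00023221 peak, and C06A1.9 on II (197). Small nuclear RNA peaks were led by sls-2.1 on II (174), R07E5.16 on III (167), sls-2.4 on I (129.5) and F08H9.10 on V (118). Those of spliced leader genes also included sls-2.2 on II (96.2) and sls-2.9 on I (85.8). The microRNA list did not pass, with 6 of 261 bound (2.30%, adjusted p = 1, Fisher's exact test), among them cel-mir-4932 on I (126), cel-mir-51 on IV (112), cel-mir-354 on I (96.1) and cel-mir-243 on IV (77.9).

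Genes for translation and histones were also bound often. Of 81 ribosomal protein genes, 20 were bound (24.7%, exact 95% interval 15.8 to 35.5, odds ratio 14.8, Fisher's exact p = 7.85e-16, adjusted p = 7.33e-15). After rpl-3, the tallest peaks were at rpl-15 on IV (247), rpl-35 on III (208) and rpl-20 on IV (202). Of 72 histone genes, 14 were bound (19.4%, odds ratio 10.9, adjusted p = 2.94e-09 by Fisher's exact test), with his-59 and his-60 on IV sharing a peak of 168, his-58 on IV at 121 and his-68 on I at 112. Of 33 translation factor genes, 4 were bound (12.1%, adjusted p = 0.0124 by Fisher's exact test): eef-2 on I (122), an elongation factor, eif-3.C on I (107), eef-1A.2 on X (81.1) and eif-2Bgamma on II (76.6). The ribosomal protein list passed under every alternative tried, and the translation factor list did not pass under 5 of 11. With the window of 500 bp upstream and 100 bp downstream, 4 histone genes were bound and that list did not pass (odds ratio 3.77, Fisher's exact adjusted p = 0.0593).

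Growth, chromatin and germline genes followed. Of 30 genes for DNA replication and the cell cycle, 6 were bound (20%, adjusted p = 0.000132 by Fisher's exact test), among them pcn-1 on IV (127), the sliding clamp, mcm-2 on II (93.6), mcm-4 on I (89.4) and rnr-1 on III (80.2). Of 32 synMuv and chromatin genes, 7 were bound (21.9%, adjusted p = 2.04e-05 by the exact test), among them lin-53 on I (140), a histone-binding protein gene, lin-9 on III (118.9), lin-54 on IV (88.5) and mrg-1 on III (75.6). Of 39 respiratory chain and ATP synthase genes, 6 were bound (15.4%, adjusted p = 0.00055, Fisher's exact test), led by cox-5B on I (146.5), cox-5A on III (137), cox-6B on III (103) and atp-5 on V (102). Of 35 germline genes, 5 were bound (14.3%, adjusted p = 0.00244, the same exact test), led by pgl-3 on V (245), pos-1 on V (106), a maternal RNA-binding protein, cbd-1 on IV (98.5) and egg-1 on III (82.9), both eggshell or egg surface genes. In replicate 2 alone none of these 4 lists passed, with 1 replication gene bound and 2 genes of each other list (odds ratios 3.95, 7.65, 6.199 and 6.95, Fisher's exact adjusted p = 0.460, 0.0977, 0.105 and 0.104). In addition, the synMuv list did not pass in replicate 1 alone (exact adjusted p = 0.0922), the respiratory list with nearest starts (exact adjusted p = 0.0771), and the germline list under circular shifts (permutation adjusted p = 0.112).

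Of 37 Argonaute and small RNA pathway genes, 5 were bound (13.5%, adjusted p = 0.0029 by Fisher's exact test), among them nrde-2 on II (135), ego-1 on I (86.3), wago-4 on II (71.9) and alg-5 on I (71.3). Heat shock protein genes were taken by the name hsp, which leaves out the Hsp70 pair F44E5.4 and F44E5.5 named above (249). Of the 22 heat shock protein genes so named, 3 were bound (13.6%, adjusted p = 0.024 by Fisher's exact test): hsp-1 on IV (158), hsp-60 on III (146.7), the mitochondrial chaperonin, and hsp-110 on III (87.9). The first of these lists did not pass under 6 of 11 alternatives, and the second under 6 of 11. In the replicate 2 list alone, 6 lists passed in place of 13. Under circular shifts of the peak list, which keep the spacing of summits on each chromosome, 9 lists passed. Those lost were translation factors, heat shock proteins, germline genes and the Argonaute list (permutation adjusted p from 0.112 to 0.184).

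A different set was seldom bound. Of 1310 chemoreceptor genes, 4 were bound (0.305%, odds ratio 0.133, Fisher's exact p = 9.49e-09, adjusted p = 4.43e-08): sre-23 on I (118.6), srh-76 on V (92.7), sri-5 on I (81.0) and srz-97 on V (78.9). In single replicates 1 was bound (odds ratios 0.0738 in replicate 1 and 0.0850 in replicate 2), and both passed. The other 13 lists without a call beside microRNAs had few bound members. They held rpn-3 on III (87.9), rpn-11 on II (80.6) and pas-5 on I (3.05) among 33 proteasome genes (adjusted p = 0.0664, Fisher's exact test), vha-18 on V (106), col-52 on I (63.6), nhr-68 on V (73.2), nhr-255 on X (68.2), zip-2 on III (78.2), ztf-15 on I (71.8), clec-57 on V (78.9) and cyp-43A1 on X (76.2). None of the members of the ceh homeobox, intestine, muscle, neuron, hypodermis or major sperm protein lists was bound, of 63, 20, 20, 25, 17 and 31 genes. With adjusted p = 1 for 5 of these and 0.911 for the ceh list by Fisher's exact test, they are too small to show a lower share. Some of the 13 passed under an alternative: proteasome genes with the window of 2000 bp upstream and 500 bp downstream (7 of 33, odds ratio 8.62, Fisher's exact adjusted p = 0.000142), and, bound less often, nuclear hormone receptors in the pooled list (0 of 269, exact adjusted p = 0.0162) and C-type lectins with that window and with a protein-coding background (1 of 240 each, exact adjusted p = 0.0227 and 0.0393).

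**Figure D3:**
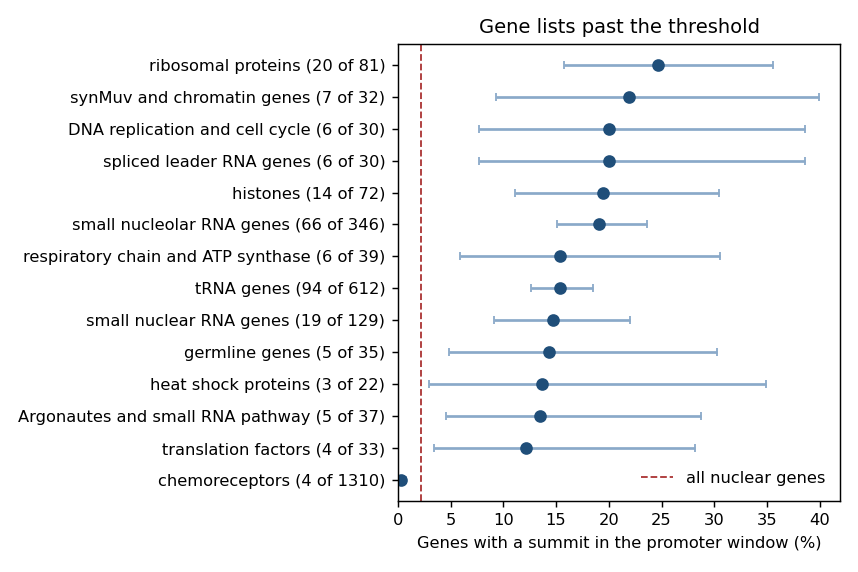
Percent of genes with a summit in the promoter window (horizontal) for the 14 lists past the threshold; points are shares, bars exact 95% intervals, and the dashed line the 2.20% of all nuclear genes. Only the chemoreceptor list (4 of 1310) lies left of the line.

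The X chromosome had few peaks. It held 67 of 1021 (6.56%, Wilson 95% interval 5.20 to 8.25) against 17.7% of genome length (exact binomial p = 3.93e-25, two-sided) and 13.7% of protein-coding genes (p = 5.92e-13). Chromosome I held 251 peaks (24.6% against 15.03% of length, exact binomial adjusted p = 5.49e-15) and III held 199 (19.5% against 13.7%, adjusted p = 8.20e-07). Chromosome V held 156 (15.3% against 20.9%, exact binomial adjusted p = 9.49e-06). Chromosomes II (156) and IV (192) did not pass (exact binomial adjusted p = 0.965 and 0.298). On the autosomes, 578 of 954 peaks (60.6%, 57.4 to 63.6) lay in the central 50% of chromosome length (exact binomial p = 6.51e-11), where 55.7% of autosomal coding genes lie (p = 0.00218 against that share).

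**Figure D4:**
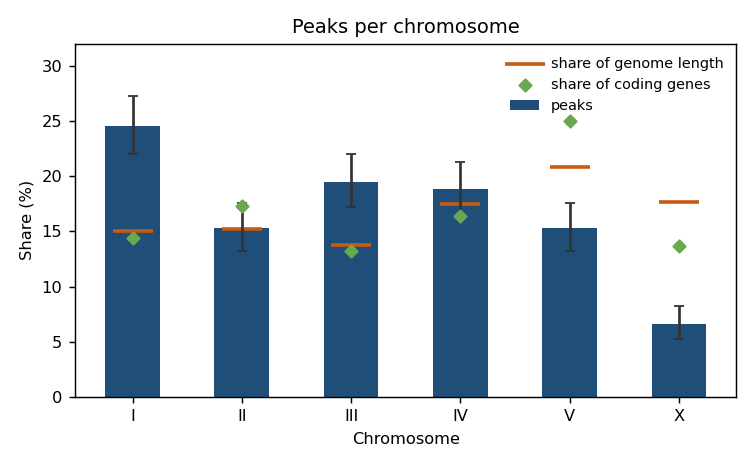
Share of the 1021 peaks on each chromosome (bars, Wilson 95% intervals) with the share of genome length (dashes) and of protein-coding genes (diamonds), in percent. Chromosome X holds 6.56% of peaks and 17.7% of length, and chromosome I 24.6% and 15.03%.

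Summits were rich in CpG-containing 6-mers. On chromosomes I, III and V (606 peaks), 81 of 2080 6-mers were more frequent at summits and 44 more frequent beside them at an adjusted p under the threshold. All 10 carried over were more frequent at summits on chromosomes II, IV and X (415 peaks). With 6-mers found anew, 5 of 10 passed in replicate 1 alone, 7 in replicate 2 alone, and 7 with sequence within 25 bp of each point. CGCGCC was at 39 summits (9.40%) and in 5 flanks (1.20%, exact McNemar p = 5.65e-08, adjusted p = 1.15e-07). ACGCGC was at 38 and in 2 (exact McNemar adjusted p = 1.49e-08), and GCGCGC at 31 and in 1 (adjusted p = 5.12e-08). CGCGCA, GCGCAC, CGCGCG, GCGCGA, GCGCCA, CGGCGC and GCACGC also passed (exact McNemar adjusted p from 5.12e-08 to 0.000192). Many of the 10 overlap one another in sequence, so 1 stretch can hold several, and a count of those passing is not a count of independent results. At least 1 of the 10 was within 50 bp of 29.2% of held-out summits and of 7.47% of flank points. Median GC content was 43.6% at summits and 37.1% in the flanks, against 35.4% in the genome.

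The gene of the tagged protein had peaks within it. Y79H2A.3 (chromosome III, 12031516 to 12052306, minus strand) held 2 conservative peaks, at 12038712 to 12039007 (signal value 84.8, with 45.4 and 38.1 in the replicate columns) and 12050046 to 12050341 (81.4, with 32.5 and 44.8). The summit of the first was intronic and that of the second in a coding exon, 2112 bp from the 5' end of the gene. The pooled list added 12041119 to 12041414 (54.3). Neither replicate's own thresholded list held a peak there. The labels describe transgenic worms that express the fusion protein. The number of copies of the gene was not tested and no input was analysed, so these peaks do not show that the protein binds its own gene.

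Peaks in promoter windows were slightly taller than others, with a median signal value of 85.6 over 649 peaks against 80.3 over 372 (permutation p = 0.00994, two-sided). The difference was -0.80 in the list of replicate 2 alone (permutation p = 0.836) and 2.12 in that of replicate 1 alone (permutation p = 0.115). It also did not pass with the window of 2000 bp upstream and 500 bp downstream (3.08, permutation p = 0.156) or among the 50% of tallest peaks (0.47, permutation p = 0.802), so it ended in 4 of 6 alternatives.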

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

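The return of left-out peaks to the gene lists was chosen after the results were seen, and the other tests here were set down before their own results were seen. In the ranked comparison of the replicates, 1065 peaks passed the IDR of the thresholded lists, and 44 of these were absent from the conservative list. The tallest of them (chromosome IV, 2828822 to 2829117, signal value 593, nearest gene clec-80) and 4 others were above the tallest peak kept (378). These were chosen after their values were seen. They were singled out because they carry signal but are absent from the list on which the comparisons of genes and regions rest.

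Explanations for the absence are technical, and no biological explanation was tested. Across the 4 lists, 170 peaks were left out, 155 of them overlapping a passing peak of another list, and 0 of 2790 thresholded summits lay inside any left-out peak. This is what removal of a fixed set of regions by the authors would give, and such a set is not described in the sources used here, though notes deposited with the data list for the thresholded lists 1 more source file of unstated content than for the ranked lists. The left-out peaks also had a median of 11.7% unique 31-mers against 100% in kept peaks (permutation p = 1e-05, the smallest possible), so reads shared between repeated copies may explain their height. The result does not exclude real binding in repeats. With these peaks put back, the same 13 lists still passed as bound more often than other genes. Then 20 small nuclear RNA genes were bound in place of 19 and 7 spliced leader genes in place of 6. No other list among the 13 gained a bound gene.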

How the results depend on the processing

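Alternatives on overlapping peaks, repeated sequence, left-out peaks, coding transcript starts only, IDR 0.05 and the lists used for the tagged gene were chosen after seeing the data. Of 68 alternative values for the main results, 55 kept their direction and their side of the threshold, or stayed within 1.5 times a count. A count of gene lists can stay within that bound while single lists lose their call. Of 150 alternative values for single lists, 124 kept their direction and call, and 24 kept their direction but lost their call. The promoter share ran from 46.8% to 76.1%, the X share from 3.82% to 6.56%, the centre share from 57.0% to 61.6% and the replicate 1 overlap from 44.8% to 58.8%. An IDR of 0.01 gave the deposited 1021 peaks again, since the list already stops there. An IDR of 0.05 in the ranked list gave 2249. Single replicates gave 393 to 442 peaks, 6 to 9 gene lists, 5 to 7 6-mers, 0 to 0 peaks in Y79H2A.3 and a height difference of -0.80 to 2.12, and fewer peaks enter each of these. Assigning each peak to its nearest start left 8 gene lists, all among the 13, and a protein-coding background left 8 of 23 tested, since 5 lists of noncoding genes drop out there, 4 of which had passed, and heat shock proteins lost their call (Fisher's exact adjusted p = 0.0509). The height difference was 0.47 among the 50% of tallest peaks and 3.08 with the 2000 bp window, and neither passed. The odds ratio of translation factors was 0 to 6.42 in single replicates, and that of heat shock proteins 0 with nearest starts; the cause was not tested. No paired analysis was possible because there is 1 group. Unknown depth limits any statement on absent peaks.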

Other observations

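The scan of gene families, the count of neighbouring summits, the piRNA count, the distance-matched placement, the comparison of unique with other tRNA genes and the comparison with noncoding genes alone were chosen after the main results were seen, while the other tests were set down before their results. Among 175 name families of at least 10 protein-coding genes, 5 were bound more often than other coding genes (2.88% bound) after adjustment by Fisher's exact test. Beside his, rpl and rps, these were the kinesin family klp (4 of 13, adjusted p = 0.0173) and the cytochrome c oxidase family cox (4 of 15, adjusted p = 0.0252, both by Fisher's exact test). The kinesin genes, picked after their values were seen, were klp-16 on I (126), klp-7 on III (96.8), klp-18 on IV (73.2) and klp-15 on I (71.9), motor proteins of spindles. Of 15363 piRNA genes, 56 were bound (0.365%, odds ratio 0.115, Fisher's exact p = 2.36e-104), although piRNA windows overlap one another and are not independent.

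Summits were clustered. Neighbouring summits lay 148 to 2000 bp apart 172 times, against a mean of 22.2 and at most 38 in random placements (permutation p = 0.002, the smallest possible). Some of these neighbours belong to overlapping peaks, since 960 of the 1021 peaks remained with overlapping peaks counted once. The count of neighbours was not repeated without them. The random placements also did not keep the share of peaks in promoters, so the size of the clustering beyond these features was not tested. Among 478 peaks in coding promoters, 125 (26.2%) lay in windows of genes on both strands, against 9.91% of random sites in such windows (permutation p = 0.002). With sites at the same distances from random starts the mean was 18.2% and the highest 24.1% (permutation p = 0.002). A preference for shared upstream regions is a hypothesis from these data.

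The high share of tRNA genes with a peak was weighed against GC content, neighbouring coding promoters and shared reads. That of snoRNA genes was weighed against GC content, coding promoters and peaks in repeated sequence. The uniqueness of the snoRNA genes' own sequence was not tested. Sites matched to the peaks on chromosome and GC content put a peak on a mean of 7.80 tRNA genes, so the observed 94 is 12.05 times that. For snoRNA genes the mean was 5.87 against 66 observed. Both results argue against GC content as the whole cause. With peaks in coding promoters left out, 73 tRNA and 38 snoRNA genes were still bound, with odds ratios of 8.48 and 6.56 against other noncoding genes without piRNA genes (16.2 and 12.8 with them), which argues against neighbouring coding promoters as the whole cause. With peaks of fewer than 50% unique 31-mers left out, 94 tRNA and 66 snoRNA genes were still bound (odds ratios 9.28 and 11.7). This argues against peaks in mostly repeated sequence as the cause for either list. Among 61 tRNA genes in sequence with at least 90% unique 31-mers, 5 were bound (odds ratio 4.32, Fisher's exact p = 0.00803). Of the other tRNA genes, 16.2% were bound (Fisher's exact p = 0.133 for the difference). That sequence was the gene with flanks of 100 bp, while a summit can lie farther upstream. Peaks that were kept can still hold some repeated sequence, so shared reads may add to the tRNA pattern but are not all of it. Open chromatin at transcribed small RNA genes stays untested, since no control precipitation was analysed here.

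Base composition was weighed as the source of the GC-rich 6-mers. In 100 shuffles of the held-out summits that keep dinucleotide counts, 6 of the 10 6-mers were in more real summits than in 95% of shuffles, and ratios over all 10 ran from 1.12 to 2.01. Sequence preference and composition cannot be told apart for the set, because the count falls between the bounds fixed for either. GCGCCA was at 34 summits against a shuffle mean of 16.9 (adjusted p = 0.0198 by permutation).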
